A study of Homo sapiens with 16 samples.

How the data were processed

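Expression was measured in OCI-AML2 cells, an established human acute myeloid leukaemia line, on the nCounter Human Immunology v2 panel, per the labels' protocols. In this assay each target RNA binds a probe with a fluorescent barcode, and the barcodes are counted without enzymatic labelling. Per the labels' protocols the cells were transduced with short hairpin RNA constructs against PNPase or SUV3, and total RNA was isolated with a commercial kit. The labels' protocols also name the preparation of cDNA, whose place in this assay is not given in the sources used here.

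The deposited values form a score whose exact making is not given in the sources used here. Only the name of 1 of the 2 deposited tables says that unwanted variation was removed by the authors. All 594 genes had identical values in the deposited tables, so that the planned use of the other table as an alternative could change nothing. The values were whole numbers that behaved as unscaled counts. The 169 genes with means from 3 to 8 had a variance of 1.02 times the Poisson expectation, and the spiked positive controls still spanned 1.47-fold between samples. The 15 housekeeping genes shared a factor that spanned 2.03-fold, with 75.8% of their variance on 1 component. The values were therefore treated as linear levels and not as ratios against control cells, and the test of each knockdown against control, planned for ratios only, was not run. Totals over all genes ranged from 311396 to 493370 per sample. The 8 negative control probes averaged 6.80 with an SD of 3.05, which limits the precision for weak genes. Of the gene symbols, 565 were current in the RefSeq gene table for GRCh38.p14, 12 were older synonyms and 17 had no match; symbols are given as the files hold them, and no coordinates are given because the files name no genome build.

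The groups, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. That plan assumed normalised log2 values, which the tables did not hold. Each sample was therefore divided by the geometric mean of the 15 housekeeping genes, centred over samples, a scaling that had been planned as an alternative, and log2(value + 1) was taken. Changes of weak genes are understated on this scale. All 594 genes were tested, as planned. A filter to the 354 genes above 12.9, the mean plus 2 SD of the negative controls, was first used for all tests after the values were seen and was then withdrawn in favour of the plan; its results are given as an alternative.

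Tests used limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with Benjamini-Hochberg adjustment and a threshold of 0.05. For PNPase against SUV3 knockdown, each replicate was averaged over its 4 days, which gave 2 against 2 values and 2 residual degrees of freedom. For the change per day, a line on day was fitted for each knockdown to all 16 samples with an intercept for each of the 4 replicates as a block. The design text states that the 4 days were taken from each of 2 biological replicates per knockdown, so the replicate numbers pair samples across days. Deviations of samples with the same number from their group means correlated across genes between days at 0.04 to 0.67 for PNPase and 0.23 to 0.60 for SUV3. A contrast of day 3 against the mean of days 4 to 6, both knockdowns averaged, was added after the values were seen.

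Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over 15 lists for each comparison. Fry tests whether the genes of a list move, on balance, in 1 direction, and does not compare the list with other genes. The lists covered interferon-stimulated genes, nucleic acid sensing, MHC class I and class II presentation, the NF-kappaB pathway, inflammatory cytokines and chemokines, myeloid differentiation markers, stem and progenitor cell genes, ligands and receptors of immune-mediated killing, apoptosis, the inflammasome, complement, JAK-STAT signalling, T cell and NK cell markers and B cell markers. Camera compared each list with the rest of an immune panel and not with the genome. The list of housekeeping genes served the scaling and was not tested as a list. The rule for named genes took, for each comparison, up to 10 genes on each side with the largest change among those past the threshold, above the negative controls and in 1 direction in both replicates, and up to 4 called members of each list. Where fewer than 5 passed, the 5 smallest p on each side were named as not passing. In addition 19 genes were always considered. Not all genes that the rule selects are reported here.

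The fits were tested on simulated data with 20 draws of 594 genes, 20 genes changed at each size. Changes were planted only in genes above the negative controls, with all sizes planted together. The rates below therefore do not cover weaker genes, and may be lower where fewer genes change. Of the calls, 4.2% were false between the knockdowns, 4.4% after PNPase and 5.4% after SUV3 knockdown. The share was 5.6% for the difference of slopes and 6.9% for the contrast of day 3. A planted change of 0.50 per day was recovered for 77.5% of genes after PNPase and 81.5% after SUV3 knockdown. In the comparison of knockdowns, a planted difference of 2 on the log2 scale was recovered for 54.8% of genes and a difference of 1 for 4.5%. The simulated genes varied independently of each other, so camera's behaviour with correlated genes was not tested. Alternatives covered scaling, filters, pseudocount, moderation, the treatment of replicates and days, and leaving out each replicate and each day. Figures were drawn with matplotlib.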

Results

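Transcripts of 579 genes of immune processes and 15 housekeeping genes were measured in 16 samples of OCI-AML2, a human acute myeloid leukaemia cell line, after knockdown of PNPase or SUV3. PNPase, encoded by PNPT1, and SUV3, a helicase encoded by SUPV3L1, act together in the degradation of mitochondrial RNA. Each knockdown had 2 replicates, which the series' design text calls biological, named here by the numbers in their labels, 545 and 1717 for PNPase and 1595 and 1727 for SUV3. What the numbers stand for is not given in the sources used here, so differences between replicates include those between hairpin constructs if the constructs differed. Each replicate was sampled on days 3, 4, 5 and 6, which gave 8 groups of 2 samples. Totals over all genes ranged from 311396 for PNPase replicate 1717 on day 3 to 493370 for the same replicate on day 6. The common housekeeping factor, which was divided out, averaged -0.34 ± 0.20 (SD, n = 4) on day 3 and 0.25 ± 0.25 (SD, n = 4) on day 6 on the log2 scale. Of all genes, 354 lay above the negative controls. PNPT1 and SUPV3L1 were not among the genes analysed here, so the knockdowns themselves could not be checked, and neither were DDX58 and MAVS. Control cells were not analysed here either, and the values below compare the knockdowns with each other and the days with each other.

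The first comparison asked how the immune transcripts differed between the knockdowns, over all days. HLA-DRA, a chain of the MHC class II molecule, had a scaled log2 value of 5.45 ± 0.14 (SD, n = 2) after PNPase and 7.28 ± 0.03 (SD, n = 2) after SUV3 knockdown, 3.56-fold higher after SUV3 knockdown. From day 3 to day 6 it fell from 7.91 to 6.59 in SUV3 replicate 1595 and rose from 6.77 to 7.82 in replicate 1727. The small SD of the SUV3 means thus hides opposite courses. MX1, an interferon-induced antiviral GTPase, was at 5.72 ± 0.43 (SD, n = 2) against 7.64 ± 1.25 (SD, n = 2). STAT2, which carries the interferon signal to the nucleus, was 2.12-fold higher after SUV3 knockdown. On the other side, the cyclin CCND3 was 2.34-fold higher after PNPase knockdown. The surface protein CD48 was higher there too, with deposited values of 22 to 148 against 11 to 21, the latter around the upper level of the negative controls, so no fold is given. For these 5 genes both replicates of 1 knockdown lay above both of the other, but none passed the test across genes.

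With limma, 0 genes passed the threshold, and 38 had an unadjusted p below 0.05, 3 of them higher and 35 lower after PNPase knockdown. The smallest adjusted p was 0.191, for HLA-DRA, with a log2 difference of -1.83 ± 0.22 (SE), PNPase minus SUV3. The replicates of the knockdowns did not overlap for 38.4% of genes, where chance gives 33.3%. The median difference over all genes was -0.15, and it was 0.12 without scaling of the samples, so small differences have no settled direction. The spiked positive controls ran from 0.02 to 0.29 after PNPase and from -0.26 to 0.01 after SUV3 knockdown, as log2 deviations from their mean. With no overlap there, a technical difference between the samples of the knockdowns cannot be told apart from the knockdowns. The other genes with the smallest p on each side, none of which passed, were IL4R at 0.55 ± 0.22 (SE), TGFB1 at 0.65 ± 0.27 (SE) and NOTCH1 at 0.53 ± 0.23 (SE), and CLEC5A at -1.24 ± 0.29 (SE) and HLA-DPA1 at -1.39 ± 0.34 (SE). HLA-DPA1, like HLA-DRA, fell from day 3 to day 6 in SUV3 replicate 1595, from 6.38 to 5.25, and rose in replicate 1727, from 5.78 to 6.67. Treating the 16 samples as independent, with no replicate block, would give 58 genes, and a random replicate block 4.

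Among the gene lists, all 20 measured interferon-stimulated genes had lower values after PNPase than after SUV3 knockdown, with a median difference of -0.60. The count rested on the scaling, since the housekeeping factor was higher after PNPase knockdown: without scaling 13 of 20 were lower, with a median of -0.33. The 14 members above the negative controls had a median of -0.80 with scaling and -0.50 without, where 10 were lower. No member passed over all genes and 0 passed adjusted over the list alone. Camera placed the list below the rest of the panel at an adjusted p of 0.000268, and this call was lost with an estimated correlation (adjusted p = 0.927) and without PNPase replicate 545 (adjusted p = 0.0616), although the median was then larger in size, at -0.72. Without SUV3 replicate 1727 the call held and the median was -0.30. Fry, which tests a list against no change and not against other genes, gave an adjusted p of 0.228. IRF7, a transcription factor of the interferon response, differed by -1.28 ± 0.37 (SE), the RNA sensor IFIH1 by -0.80 ± 0.28 (SE), and BST2 by -0.79 ± 0.47 (SE). The list of MHC class II presentation, with 12 of 15 members lower after PNPase knockdown and a median of -0.39, had a camera adjusted p of 0.0115. Over all genes 0 members passed, and 4 passed adjusted over the list alone. This call too was lost with an estimated correlation (adjusted p = 0.927), and the adjusted p without each replicate ranged from 0.0456 to 0.133, with medians from -0.54 to -0.35.

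The list of MHC class I presentation had a median difference of 0.00 and a camera adjusted p of 0.614. This median was not stable: it was 0.24 without SUV3 replicate 1727 and -0.30 without SUV3 replicate 1595. HLA-B differed by -0.15 ± 0.32 (SE), HLA-C by 0.02 ± 0.28 (SE), B2M by -0.27 ± 0.31 (SE) and the peptide transporter gene TAP1 by 0.07 ± 0.28 (SE). The monocyte marker CD14 differed by 0.11 ± 0.55 (SE) and ITGAM, the integrin chain CD11b, by -0.31 ± 0.32 (SE). None of these 6 passed, and their errors leave room for differences in either direction. IFNB1 and CD34 averaged 4.19 each and IFIT2 12.6 in the deposited values, not above the negative controls. The remaining 12 lists had camera adjusted p from 0.646 to 0.983. Of the 48 T cell and NK cell markers 5, and of the 16 B cell markers 7, lay above the negative controls.

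**Figure D1:**
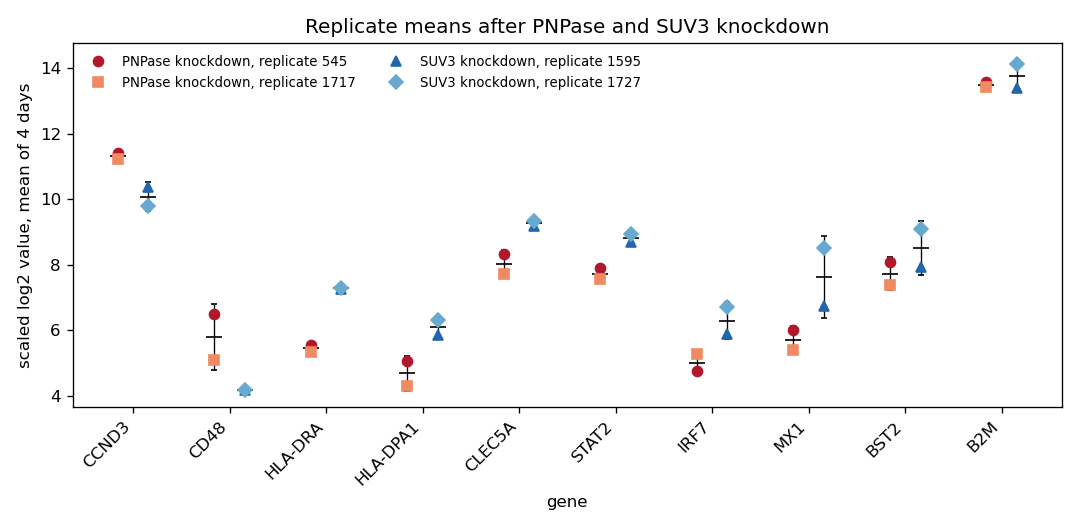
Scaled log2 value of each replicate, averaged over its 4 days, for 10 genes, with the mean (black dash) and SD (black bar, n = 2) of each knockdown. HLA-DRA sits at 5.45 after PNPase and 7.28 after SUV3 knockdown, while B2M overlaps between the knockdowns.

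The next comparison asked which transcripts changed from day 3 to day 6 after SUV3 knockdown. IRF7 fell to 0.671 of its level per day, a slope of -0.57 ± 0.08 (SE) on the log2 scale with an adjusted p of 0.00913. EGR1, an immediate early transcription factor, fell by 0.55 ± 0.11 (SE) per day, and BCL3, a regulator of NF-kappaB, by 0.51 ± 0.11 (SE). From day 3 to day 4, EGR1 went from 5.53 to 4.63 in replicate 1595 and from 7.06 to 5.51 in replicate 1727. BCL3 went from 6.01 to 4.47 and from 5.35 to 4.99. Both were also called higher on day 3 in the later contrast over both knockdowns, so a steady fall particular to SUV3 was not shown. The cytokine IL32 fell by 0.38 ± 0.07 (SE) per day and the survival factor MCL1 by 0.23 ± 0.05 (SE). ICAM4, an adhesion molecule, fell too. Its deposited value was 11 on days 5 and 6 in replicate 1727. This lies below the upper level of the negative controls of 12.9, so no slope is given for ICAM4. In all 6 the slope had the same sign in both replicates, which the rule for naming required. In the plot of values per day, IRF7 went from 6.87 to 4.91 in replicate 1595 and from 7.59 to 5.97 in replicate 1727.

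In limma, 10 genes passed, all of them lower on later days, and 84 had an unadjusted p below 0.05. CXCR6, ITGA6 and LIF, which were among the 10, had mean deposited values from 3.63 to 12.1, near the negative controls, and were named after their values were seen. The adjusted p of the 5 named genes besides IRF7 lay between 0.0293 and 0.0451. MX1 had a slope of -0.56 ± 0.13 (SE; adjusted p = 0.0516), which did not pass, and neither did CD14 at 0.27 ± 0.11 (SE). The count depended on single replicates and days: it was 0 without replicate 1595, 2 without replicate 1727, 2 without PNPase replicate 545, 1 without PNPase replicate 1717, and 0 without day 3, day 5 or day 6. It was also 0 with no replicate block and 0 without scaling, where the median slope went from -0.05 to 0.09.

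Of 20 interferon-stimulated genes, 19 had negative slopes after SUV3 knockdown, with a median of -0.24 per day. IRF7 alone passed over all genes, and 7 passed adjusted over the list alone. Camera gave the list an adjusted p of 5.88e-05 and fry 0.00669, whereas the estimated correlation ended the call (adjusted p = 0.402). With camera the adjusted p stayed below the threshold without each replicate and without each day, the highest being 0.037, without SUV3 replicate 1595. The median slope was then -0.16, and it was -0.15 without day 3. The 44 myeloid differentiation markers had a median slope of -0.01 and a mean of 0.01, 21 of them above 0, against a panel median of -0.05. Camera placed this list above the rest of the panel (adjusted p = 0.0151), although 0 members passed, over all genes or adjusted over the list alone, and the estimated correlation ended the call (adjusted p = 0.913). The SUV3 replicates went opposite ways: the median was 0.21 without replicate 1595, where camera's adjusted p was 9.11e-06, and -0.13 without replicate 1727, where the list lay below the rest of the panel (adjusted p = 0.728). The call was also lost without day 3 (adjusted p = 0.199), without day 6 (adjusted p = 0.0939), without scaling (adjusted p = 0.0731) and with the negative controls subtracted (adjusted p = 0.0843). The other 13 lists had camera adjusted p of 0.133 or more. Among called members in them were BCL3 of the NF-kappaB list, IL32 and LIF of the cytokines, ICAM4 of the ligands of immune-mediated killing and MCL1 of the apoptosis list. Adjusted over the list alone, 3 genes passed in the NF-kappaB list, 3 B cell markers, 2 cytokines, 2 apoptosis genes, 2 JAK-STAT genes, 1 gene of immune-mediated killing and 1 of nucleic acid sensing.

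**Figure D2:**
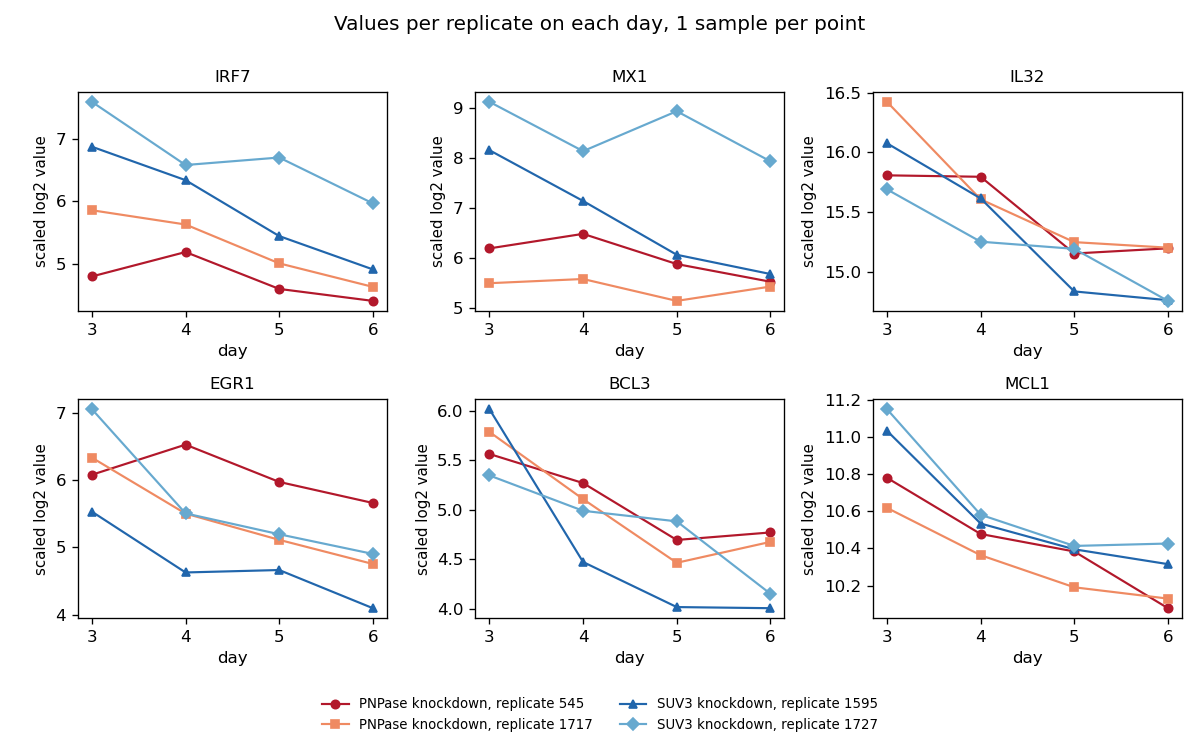
Scaled log2 value on days 3 to 6 for 6 genes, 1 point per sample and 1 line per replicate, with a separate vertical scale for each gene. IRF7 fell in both SUV3 replicates, from 6.87 to 4.91 and from 7.59 to 5.97, and MX1 did not pass the test after either knockdown.

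The same question was asked of PNPase knockdown. No gene above the negative controls passed. The cytokine IL32 had a slope of -0.32 ± 0.07 (SE) per day, the chemokine IL8 of -0.71 ± 0.16 (SE) and the lectin receptor CLEC4E of -0.42 ± 0.09 (SE). The lowest deposited value of CLEC4E was 12, in replicate 545 on day 6. ICAM1 and FCER1A, a chain of the IgE receptor, also had negative slopes. Each of these genes had an adjusted p of 0.0618. In replicates 545 and 1717, ICAM1 had deposited values of 12 and 8 on day 5, and FCER1A 12 and 10 on day 6. These lie below the upper level of the negative controls of 12.9, so no slope is given for ICAM1 and FCER1A. The smallest p with a positive slope belonged to ITGA2B, the platelet integrin chain (adjusted p = 0.0645). Its mean deposited value of 14.1 lay just above the negative controls, with values down to 5, so no slope is given. CD3EAP at 0.27 ± 0.09 (SE), JAK3 at 0.17 ± 0.07 (SE) and CLEC5A at 0.19 ± 0.08 (SE) followed and did not pass. IRF7 had a slope of -0.30 ± 0.08 (SE; adjusted p = 0.0767), and those of HLA-B, HLA-C and B2M lay between -0.13 and -0.08.

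In limma, 1 gene passed, IL17A at -0.50 ± 0.07 (SE; adjusted p = 0.00574), with a mean deposited value of 9.31 that is not above the negative controls. An unadjusted p below 0.05 was found for 131 genes, 10 with a positive and 121 with a negative slope. Without scaling, 120 genes passed, 114 of them with a positive slope, and the median slope over all genes was 0.13 in place of -0.10, so the direction of the panel as a whole rested on the housekeeping genes. The count was 1 with no replicate block, 7 with a random replicate block, 0 without replicate 545, without replicate 1717 or without SUV3 replicate 1727, 10 without SUV3 replicate 1595, 17 without day 4 and 0 without day 3, day 5 or day 6. None of the 15 lists passed with camera, the smallest adjusted p being 0.249, whereas fry called 10, all with negative slopes. The interferon-stimulated genes were among these 10 (fry adjusted p = 0.0263). As after SUV3 knockdown, 19 of their 20 slopes were negative, here with a median of -0.15 per day. Adjusted over the list alone, 5 cytokines and chemokines, 3 B cell markers, 3 myeloid markers, 2 JAK-STAT genes, 3 complement genes, 1 gene of immune-mediated killing and 1 of apoptosis passed with negative slopes, and 1 complement gene with a positive slope.

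The difference of the slopes was tested directly. Limma called 0 genes, 39 had an unadjusted p below 0.05, and the smallest adjusted p was 0.0896. ITGA2B, with a positive slope after PNPase and a negative one after SUV3 knockdown, had the smallest p above the negative controls. Its deposited values from 5 to 43 reach below the upper level of the negative controls, so no size is given. JAK3 at 0.29 ± 0.09 (SE), IRF7 at 0.27 ± 0.12 (SE) and MX1 at 0.40 ± 0.18 (SE) followed on the positive side. So did LY96, given without a size for the same reason, with deposited values from 5 to 28. IL4R at -0.19 ± 0.07 (SE), DEFB1 at -0.49 ± 0.20 (SE), CLEC4E at -0.30 ± 0.13 (SE) and ITGB2 at -0.23 ± 0.10 (SE) had the smallest p on the negative side. With them was ICAM1, whose deposited values from 8 to 22 again allow no size. None of these genes passed. The interferon-stimulated genes had a median difference of 0.10 per day, with 15 of 20 members less negative after PNPase than after SUV3 knockdown. Camera gave an adjusted p of 0.00348, lost with an estimated correlation (adjusted p = 0.553), and 0 members passed, over all genes or adjusted over the list alone. Fry's test against no difference gave an adjusted p of 0.503. The camera call was also lost without PNPase replicate 1717 (adjusted p = 0.397), without SUV3 replicate 1595 (adjusted p = 0.209), without day 3 (adjusted p = 0.308) and without day 6 (adjusted p = 0.276), with medians then between 0.03 and 0.06. Across genes, which are not independent replicates, the slopes of the knockdowns correlated at 0.49 (Pearson) and 0.41 (Spearman). Those of the PNPase replicates correlated at 0.36 (Pearson) and 0.33 (Spearman), and those of the SUV3 replicates at 0.18 (Pearson) and 0.13 (Spearman).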

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

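The tests in this part were planned, apart from those of the list without a replicate or a day, which were added after the values were seen. The interferon-stimulated genes were singled out because camera placed their difference in change per day between the knockdowns above the rest of the panel. Fry, which tests a list against no difference, gave them an adjusted p of 0.503. Their median difference was 0.0991 per day on the log2 scale, PNPase minus SUV3, with a camera adjusted p of 0.00348. The call was lost with an estimated correlation (adjusted p = 0.553) and without PNPase replicate 1717 (adjusted p = 0.397), SUV3 replicate 1595 (adjusted p = 0.209), day 3 (adjusted p = 0.308) or day 6 (adjusted p = 0.276), where the median was between 0.03 and 0.06.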

How the results depend on the processing

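Scaling on housekeeping genes and every alternative named here as added was chosen after the values were seen: no scaling, scaling on the positive controls, centring on the median of the detected genes, subtraction of the negative controls, the restriction to genes above them, and the contrast of day 3. For lists, quantile normalization, the pseudocount and the fits without a replicate or day were also added. The cause was not tested for any result that changed. Leaving out a replicate leaves 1 for its knockdown, which is then assumed to vary like the others.

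The count for PNPase against SUV3 knockdown was 0 and became 4 with a random replicate block and 58 with samples taken as independent and no replicate block. All other alternatives, each day alone included, gave 0.

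For the change per day after PNPase knockdown, the count of 1 became 0 with each sample centred on its median, 1 gene of the other direction with quantile normalization, 12 without the weakest 33.3% of genes and 14 with trend and robust moderation. It was 0 without replicate 545, 0 without replicate 1717, 10 without replicate 1595 and 0 without replicate 1727. It was 0 without day 3, 17 without day 4, 0 without day 5 and 0 without day 6. It was 1 with no replicate block, 7 with a random replicate block, 30 for day 6 minus day 3 and 11 with the 8 samples of the knockdown only. Among added alternatives it was 120 without scaling, 114 of them positive, 156 with scaling on the positive controls, 150 of them positive, 13 with only genes above the negative controls, 0 when centred on the detected genes and 80 for day 3 against later days. B2M, which had not passed at -0.08 per day, turned to 0.21 and passed with scaling on the positive controls.

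After SUV3 knockdown, the count of 10 became 2 with each sample centred on its median, 3 with quantile normalization, 23 with a pseudocount of 20 and 26 with trend and robust moderation. It was 2 without replicate 545, 1 without replicate 1717, 0 without replicate 1595 and 2 without replicate 1727, of which 1 was among the 10. It was 0 without day 3, 0 without day 5 and 0 without day 6. It was 0 with no replicate block, 21 for day 6 minus day 3 and 0 with the 8 samples of the knockdown only. Among added alternatives it was 0 without scaling, 0 with scaling on the positive controls, 21 with only genes above the negative controls, 4 with the negative controls subtracted and 47 for day 3 against later days. IRF7 passed in 14 of 23 alternatives, EGR1, BCL3 and MCL1 in 9 each, IL32 in 8 and ICAM4 in 6.

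For the difference of slopes, the count of 0 became 2 without the weakest 33.3% of genes, 1 without replicate 545, 1 without day 3, and among added alternatives 1 without scaling, 1 with only genes above the negative controls, 1 with scaling on the positive controls and 1 with the negative controls subtracted. With no replicate block it stayed 0.

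For day 3 against days 4 to 6, 133 genes became 173 with each sample centred on its median, of which 33 were higher on day 3, and 91 with quantile normalization, of which 40 were higher. The count was 72 without replicate 545, 52 without replicate 1717, 80 without replicate 1595 and 99 without replicate 1727. It was 56 without day 5 and 73 without day 6. It was 178 without scaling, 27 of them higher on day 3, and 169 with scaling on the positive controls, 25 of them higher.

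Lists past the threshold between the knockdowns were 2, and 0 with an estimated correlation, 0 with fry, 1 with a pseudocount of 20, 1 without replicate 545, 1 without replicate 1717, 1 without replicate 1595, 2 without replicate 1727, where MHC class I presentation replaced class II (adjusted p = 0.0618) with the other direction, 1 without day 4 and 1 without day 6. For the change per day after PNPase knockdown they were 0, and 10 with fry and 1 with scaling on the positive controls. After SUV3 knockdown they were 2, and 0 with an estimated correlation, 4 without replicate 1595, where MHC class II and the NF-kappaB pathway joined, 1 without replicate 1727, 1 without day 3, 1 without day 6, 1 without scaling and 1 with the negative controls subtracted. For the difference of slopes the count of 1 became 0 with an estimated correlation, 0 with fry, 2 with each sample centred on its median, 2 with quantile normalization, 3 without the weakest 33.3% of genes, 3 with a pseudocount of 20, 0 without replicate 1717, 3 without replicate 1595, none of them the interferon-stimulated genes, 0 without day 3, 2 without day 4, 2 without scaling, 3 with only genes above the negative controls, 2 with scaling on the positive controls and 3 when centred on the detected genes. Without day 6 it stayed 1, with the NF-kappaB pathway (adjusted p = 0.0427) in place of the interferon-stimulated genes. Counts with fry answer another question than camera's, since fry does not compare a list with other genes.

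Of 1801 alternative values of named genes, 1626 kept their call or lack of one, but 136 of these changed sign with no call either way. A call was lost by 83, 21 of these when a replicate was left out. A further 91 gained a call and 1 turned direction with a call.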

Other observations

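The contrast in this part was chosen after the values per day were seen. Day 3 stood apart from days 4 to 6 after both knockdowns. CDKN1A, the cell cycle inhibitor p21 induced by p53, was 18.9-fold higher on day 3, a log2 difference of 4.24 ± 0.25 (SE; adjusted p = 2.96e-07) with values of 3.76 to 5.11 in the 4 replicates. FAS, a death receptor and also a p53 target, was 3.42-fold higher. PTGS2 was 3.70-fold, NFKBIZ 3.55-fold and PRDM1 3.50-fold higher. The chemokines CCL3 and CCL4, FCER1A, IL21R and TNFRSF10C, a decoy receptor for the death ligand TRAIL, were higher too. On later days their deposited values were 10 to 25, 4 to 19, 5 to 24, 10 to 21 and 12 to 53, which reach down to or below the upper level of the negative controls of 12.9, so no fold is given. Lower on day 3 were the chemokine receptor CCR2, which rose 2.41-fold later, IL1B at 2.13-fold, and the haematopoietic transcription factors IKZF1 at 1.78-fold and GFI1 at 1.55-fold. CD3EAP at 1.75-fold, FCGR1A/B at 1.58-fold, IL16 at 1.46-fold and POLR1B, itself a housekeeping gene of the panel, at 1.51-fold were also higher later, as was CD209, whose day 3 values of 9 to 15 were near the negative controls. Having 1 direction in all 4 replicates was a condition for being named here, so it lends these genes no further support. For IL16 the difference in replicate 1595 was only -0.04.

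In limma, 133 genes passed, 102 higher and 31 lower on day 3. Of these 133, only 107 lay above the negative controls. The balance of directions rested on the scaling, with 33 higher and 140 lower when each sample was centred on its median, 27 higher and 151 lower without scaling, and 25 higher and 144 lower with scaling on the positive controls. For the difference of this contrast between the knockdowns, limma called 0 genes (49 with an unadjusted p below 0.05). Of the lists, interferon-stimulated genes had 7 of 20 members higher and 0 lower, inflammatory cytokines and chemokines 11 of 34 higher and 2 lower, ligands and receptors of immune-mediated killing 8 of 25 higher and 0 lower, and stem and progenitor cell genes 1 of 13 higher and 3 lower. Camera called 0 of the 15 lists, with a smallest adjusted p of 0.0879, so these counts do not set the lists apart from the panel.

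For the genes higher on day 3, an explanation from the samples' scale was weighed first. The housekeeping factor was lowest on day 3, at -0.34. The spiked positive controls did not share this. Their log2 deviations averaged 0.01 on day 3 and 0.02, -0.06 and 0.02 on days 4, 5 and 6. This argues against a lower counting efficiency on day 3, although spiked controls do not measure the amount of sample RNA. Only 26.5% of the 102 genes stayed past the threshold as higher on day 3 without scaling. That was under the bound of 50% fixed beforehand, on the side of scale as the cause. The outcome was then read as undecided, because leaving out the scaling moves all genes of a sample alike. Scale cannot be the whole of it for the 27 genes that were higher on day 3 without any scaling too, CDKN1A, FAS, CCL3 and CCL4 among them, a test chosen after the result was seen. Background counts of weak probes are argued against by 67.6% of the genes staying past the threshold after subtraction of the negative controls, also chosen after the result. A test fixed before its value was seen found 40.2% of genes above 10 times the negative control mean, on the side of background under its bound of 50%; the 95% exact interval, added afterwards, ran from 30.6% to 50.4%, so it was read as undecided. Of 100 draws that gave 1 odd day to each replicate, 1, the real one, reached 133 genes, and the highest other gave 7. Day 3 had been chosen after the values per day were seen, and the draws did not repeat that choice. Draws with other odd days also left the day 3 change in the residual spread, which lowers their counts. They therefore cannot say how often chance would set 1 day apart. Whether the knockdowns, transduction or handling account for day 3 was not tested, since control cells were not analysed here.

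The higher values of interferon-stimulated genes after SUV3 knockdown were weighed as the second pattern. The list's median of -0.60 lay below all 10000 random lists matched on mean level, the lowest of which was at -0.48, a percentile of at most 0.01. A scale difference common to all genes would move such lists alike, so this argues against scale as the whole cause. Camera had already set the list apart from the panel on the same values, so the random lists lend it no further support. They also ignore correlation between its genes. Without scaling the list's median was -0.33. The test of whether 1 replicate carries the result was whether camera's call held without each replicate. The call was lost without PNPase replicate 545, on the side of 1 replicate carrying it. The outcome was then read as undecided because of the list's medians. The highest camera adjusted p without 1 replicate was 0.0616, without PNPase replicate 545, but the median was then -0.72; it was -0.67 without replicate 1717, -0.89 without replicate 1595 and -0.30 without replicate 1727, and these medians were used after the adjusted p was seen. The 3 splits of 4 replicates into pairs cannot give a share below the threshold; the real split gave the largest median size, which 1 of 3 splits reached, against 0.24 for the highest other. The positive controls differed between the knockdowns by 0.29 on the log2 scale, with no overlap. A technical difference between the samples of the knockdowns therefore cannot be told apart from the knockdowns. No biological explanation was tested.

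For the counts of genes with a change per day, the days were shuffled within replicates in 100 draws, the real order included. After SUV3 knockdown 1 of 100 draws, the real one, gave 10 genes, and the highest other gave 0, which argues against chance ordering. After PNPase knockdown 13 of 100 gave at least 1 gene, with up to 4, so chance is not excluded there. For the difference of slopes the real count was 0, which every draw reaches, so the shuffles, with up to 2 genes, decide nothing.

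Replicates of 1 knockdown differed from each other nearly as much as the knockdowns did. Of the sum of squares over all genes, 26.1% lay between replicates of a knockdown, 14.6% between knockdowns and 26.1% between days, or 13.1%, 14.6% and 8.70% per degree of freedom. The alarmin gene S100A8 averaged 12.62 in PNPase replicate 545 and 12.93 in SUV3 replicate 1727, but 10.51 in replicate 1717 and 10.69 in replicate 1595, and S100A9 was likewise higher in 545 and 1727, at 13.38 and 13.99, than in 1717 and 1595, at 11.63 and 11.29. S100A8 and S100A9 were not selected by the rule for named genes and were picked after their values were seen. Setting 545 and 1727 against 1717 and 1595 gave 4 genes past the threshold, where the real split gave 0. The remaining split, 545 and 1595 against 1717 and 1727, also gave 0. Whether the replicate numbers stand for different constructs is not given in the sources used here, and an effect of construct was not tested.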
